A study of Caenorhabditis elegans with 4 samples.

How the data were processed

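ChIP-seq of T26A5.5 was analysed from 4 samples of N2 early embryos, 2 ChIP and 2 input, with replicates 1 and 2 of each kind named in the labels. Per the labels' protocols, frozen and ground embryos were crosslinked for 10 min in 1% formaldehyde, sonicated and immunoprecipitated. The labels describe different library preparations for the kinds of sample: input libraries were size-selected on a Pippin instrument, and ChIP libraries had indexed adaptors and bead purification. The series name and its design text carry different antibody codes for the same target, so the antibody is described here only by its target.

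Per the submitters' processing notes, BWA and the genome ce10 were used, with no role or version given. Per the file headers, peak coordinates are in WormBase WS220. Per the files' source column, the replicate lists were made with MACS and the series-wide list with MACS v2; the cut-offs, the control used, and whether the series-wide list came from pooled reads are not given in the sources used here. The deposited files give each peak a score from the authors' peak calling, and the headers do not state its unit. The score ran from 50.08 to 3217.62 in replicate 1, from 50.01 to 3233.06 in replicate 2 and from 1.30 to 120.44 in the series-wide list, so it was used only to rank and describe peaks within a list. The files hold no read counts, and depth is unknown. Wilson 95% intervals of shares of peaks cover counting error only, and neighbouring peaks are not independent. Since the labels do not say that replicates were separate cultures, p-values measure only how these lists differ from shifted or permuted positions.

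Lists were compared with 1-based coordinates and an overlap of at least 1 bp. Chance overlap came from 1000 circular shifts of a list within each chromosome by at least 100 kb, with chromosome length taken as the highest peak end in any list. For support by both replicates the series-wide list was shifted against the replicate lists, a background added after the data had been examined, and the replicate lists were also shifted separately. The supported set is the series-wide peaks that overlap a peak of replicate 1 and a peak of replicate 2. Densities were counted by peak midpoint in 1 Mb bins. Chromosome centres are bins with a midpoint between 25% and 75% of the chromosome's length, and arms are the other bins. Bins were permuted with 100000 resamples, two-sided, or listed exactly where all splits came to no more than that number. SDs of densities leave out end bins shorter than 0.5 Mb, which remain in the densities and tests. The peaks named in the report are the 20 supported peaks with the highest series-wide score, with ties ordered by chromosome and start. The sample groups, comparisons, tests, the naming rule and a first set of alternatives were fixed before the data were examined.

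The alternatives were reciprocal overlap of 50% of each peak, midpoints within 200 bp, peaks at or above the median score, lists of equal length, uniform random placement, 500 kb bins, each replicate alone and all series-wide peaks. After the data had been examined, further alternatives were added: base pairs covered, autosomes only, leaving out each autosome in turn, centre or arm bins only, permutation within each autosome, and the arm to centre ratio of X in each list. The tests of peak ratios between the replicate lists, made on the replicate 2 share of the summed peaks, were also added then.

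The gene-level comparisons fixed at the start were not analysed here. They cover promoter share, annotation classes, bound genes, 23 gene lists, non-coding RNA genes, CpG content and divergent promoters. No WS220 genome or annotation was used here, and the WBcel235 gene table supplied only the name jhdm-1. The step of overlap was tested on simulated lists of uniformly placed peaks, and the step of density on simulated, independent bin counts. Unrelated lists were called overlapping in 2% of 100 simulated pairs, and a planted shared share of 60% was recovered as 60.0% on average in 20 sets. A planted halving of X density was called in 100% of 100 sets, and no difference was called as one in 1% of 100. The simulations held no clustering of peaks, no correlation between neighbouring bins and no difference among autosomes. Their error rates therefore need not hold for these lists. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.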

Results

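T26A5.5, the protein encoded by jhdm-1 in the WBcel235 gene table and a relative of the mammalian KDM2 family of JmjC-domain histone demethylases, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in early embryos of the wild-type C. elegans strain N2. ChIP-seq recovers the DNA that is crosslinked to a protein, and regions with more ChIP reads than a control are reported as peaks. The series held 4 samples, 2 ChIP samples and 2 input samples of chromatin DNA without immunoprecipitation. The embryos came from a mixed population of males and hermaphrodites kept at 20 °C. The values analysed were 3 peak lists, 1 for each ChIP replicate and 1 for the whole series. The lists give an interval and a score for each peak and no read counts, so the depth behind each list is unknown, and the inputs enter only as far as the authors used them in calling peaks. Nothing in the labels says that the replicates came from separate cultures.

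Peaks lay on all 6 nuclear chromosomes in each list. The replicate 1 list held 4200 peaks with a median width of 1735 bp (interquartile range 1299 to 2864 bp) covering 10.4 Mb. The replicate 2 list held 6563 peaks with a median width of 1307 bp (interquartile range 933 to 2361 bp) covering 13.4 Mb. The series-wide list held 12350 narrower peaks with a median width of 386 bp (interquartile range 238 to 642 bp) covering 6.82 Mb. Relative to the highest peak end on each chromosome, these peaks covered 10.3%, 13.3% and 6.80% of the span.

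The regions with the highest scores in the series-wide list that both replicates supported were spread over every chromosome. Of the 20 highest, 3 lay on I, 2 on II, 5 on III, 5 on IV, 2 on V and 3 on X (WS220 coordinates throughout). The highest score, 120.44, was shared by 9 of them. These were II 12787594 to 12791225, III 341672 to 349799, III 7142040 to 7142514, III 12596469 to 12602241, IV 3336434 to 3338914, IV 9511061 to 9511942, V 14092371 to 14092796, X 6616828 to 6622924 and X 16929241 to 16943487. The last was also the widest supported peak, at 14247 bp, and V 14092371 to 14092796 was the narrowest of the 20, at 426 bp. The other 11 had scores from 115.79 to 119.95 and were, in falling order, I 1698152 to 1702229, IV 17087529 to 17089321, IV 9140234 to 9140673, I 6283504 to 6289943, V 20698653 to 20699131, X 16564498 to 16564976, I 8133791 to 8135474, IV 9463463 to 9464737, II 14018031 to 14018506, III 11123528 to 11124249 and III 12366977 to 12369054. All 20 met a replicate 2 peak with a score of 3100, and 12 of them met a replicate 1 peak with that score. The score of 3100 was repeated in 959 of 6563 replicate 2 peaks and 378 of 4200 replicate 1 peaks, so it does not single out these regions. The lowest replicate 1 score among the 20 was 1233.85, at X 16564498 to 16564976. These intervals were not assigned to genes, because no WS220 annotation was used here.

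The overlap of the replicate lists measures how far the same regions were called in both ChIP samples. Of the replicate 1 peaks, 3439 of 4200 overlapped a replicate 2 peak by at least 1 bp (81.9%, Wilson 95% interval 80.7 to 83.0). Of the replicate 2 peaks, 3712 of 6563 overlapped a replicate 1 peak (56.6%, 55.4 to 57.8). When the other list was shifted around each chromosome 1000 times, the mean overlap was 26.5% for replicate 1 peaks and 18.6% for replicate 2 peaks, and the highest was 28.7% and 20.1%. The observed overlap was 3.09-fold and 3.04-fold above these means (one-sided permutation p = 0.001 in each direction, the smallest that the shifts can give). With lists of equal length, the 4200 highest-scored peaks of each replicate, the overlap was 68.1% for replicate 1 and 69.5% for replicate 2. The shifted means were 20.4% and 20.5%. Requiring midpoints within 200 bp left fewer peaks shared, 1772 of 4200 in replicate 1 (42.2%) and 1772 of 6563 in replicate 2. Under that rule the shifted means were also lower, at 2.82% and 1.81%, and the observed shares were 15.0-fold and 14.9-fold above them.

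Peaks found in both replicates had a higher median score than peaks found in one. It was 562 for shared and 165 for unshared replicate 1 peaks, and 827 for shared and 182 for unshared replicate 2 peaks. Across the 3439 replicate 1 peaks with a replicate 2 partner, the scores of the partners were correlated with a Spearman rho of 0.537 (bootstrap 95% interval 0.509 to 0.564). This correlation is across peaks, which are not independent replicates, and the score of 3100 was repeated in 378 replicate 1 and 959 replicate 2 peaks.

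Of the series-wide peaks, 6097 of 12350 overlapped a peak of both replicates (49.4%, Wilson 95% interval 48.5 to 50.3), against a mean of 10.5% and a maximum of 11.7% when the series-wide list was shifted and the replicate lists stayed in place relative to each other. With the replicate lists shifted separately, which removes their overlap with each other, the mean was 2.64% and the maximum 4.62%. The series-wide list belongs to the same series as the replicate lists. Its overlap with them therefore describes how the lists relate and is not independent evidence of replication. A further 2923 (23.7%) met a replicate 2 peak only, 1464 (11.9%) a replicate 1 peak only, and 1866 (15.1%) neither. Peaks met by both replicates were the widest and highest-scored, with a median width of 567 bp and a median score of 22.06. Those met by neither had a median width of 229 bp and a median score of 5.03. In the lowest 10% of the list by score 37.0% of peaks had support from both replicates, and in the highest 10% the share was 95.2%. The lowest share, 27.7%, was among scores from 5.30 to 7.02. In the other direction, 4163 of 4200 replicate 1 peaks (99.1%, 98.8 to 99.4) and 5402 of 6563 replicate 2 peaks (82.3%, 81.4 to 83.2) met a series-wide peak. Several series-wide peaks overlapped the same replicate peak for 1695 replicate 1 peaks (40.4%) and 1834 replicate 2 peaks (27.9%), with at most 14 and 20 for one peak.

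**Figure D1:**
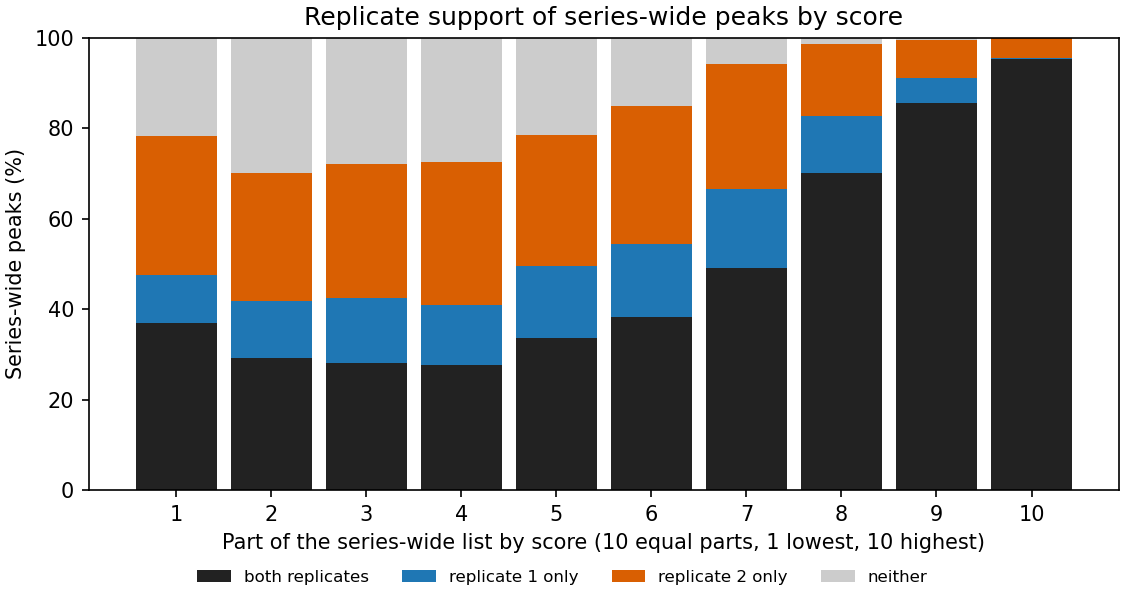
Bars give the percentage of series-wide peaks in each of 10 equal parts of the list by score that overlap peaks of both replicates, of one replicate or of neither. Support from both replicates was 37.0% in the lowest part, 27.7% in part 4 and 95.2% in the highest.

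Supported peaks were densest on chromosome III, with 91.7 per Mb, followed by I (82.7), II (74.2), IV (57.9) and V (41.8), and were sparsest on X, with 32.3 per Mb. These densities count series-wide intervals, several of which can overlap the same replicate peak. In 1 Mb bins, X held 32.3 supported peaks per Mb (SD 11.3, 18 bins) and the autosomes 67.0 (SD 26.4, 85 bins), a ratio of 0.482 (two-sided permutation test over bins, p = 1e-05, the smallest that 100000 resamples can give). The ratio was 0.448 in chromosome centres (permutation p = 3e-05) and 0.522 in chromosome arms (permutation p = 0.00273). The median score of supported peaks was 18.17 on X and ranged from 21.19 to 23.44 on the autosomes. Neighbouring bins are not independent, and with X as 1 chromosome against 5 autosomes the smallest exact p is 0.167. The read coverage of X and of the autosomes in embryos of this mixed population of males and hermaphrodites is unknown. Densities were not adjusted for coverage or gene content. Less binding on X therefore cannot be told apart from fewer reads on X.

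The gap between X and the autosomes was smaller in replicate 2 than in replicate 1. The X to autosome ratio was 0.512 in the replicate 1 list (23.5 against 45.9 peaks per Mb, permutation p = 1e-05) and 0.734 in the replicate 2 list (50.5 against 68.8, permutation p = 0.00051). In the replicate 2 list X was denser than V, which had 47.4 peaks per Mb. The ratio of X to autosomes in that list was 0.577 in chromosome centres (40.2 against 69.7 peaks per Mb, permutation p = 2e-05) and 0.900 in chromosome arms (61.0 against 67.8, permutation p = 0.362). Replicate 2 had 2.15 peaks for each replicate 1 peak on X and 1.50 on the autosomes. After the densities had been seen, the replicate 2 share of the summed peaks of both lists was tested over the same bins. It differed between X and the autosomes (two-sided permutation p = 1e-05, the smallest possible). The p-values for arms and centres that follow are for the same share. On X the excess was larger in the arms, with 2.60 replicate 2 peaks per replicate 1 peak, than in the centre, with 1.72 (9 bins each, exact permutation p = 0.00136). The same held on the autosomes, with 1.70 in the arms and 1.34 in the centres (permutation p = 1e-05). These are comparisons of the 2 lists, with 1 library each.

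**Figure D2:**
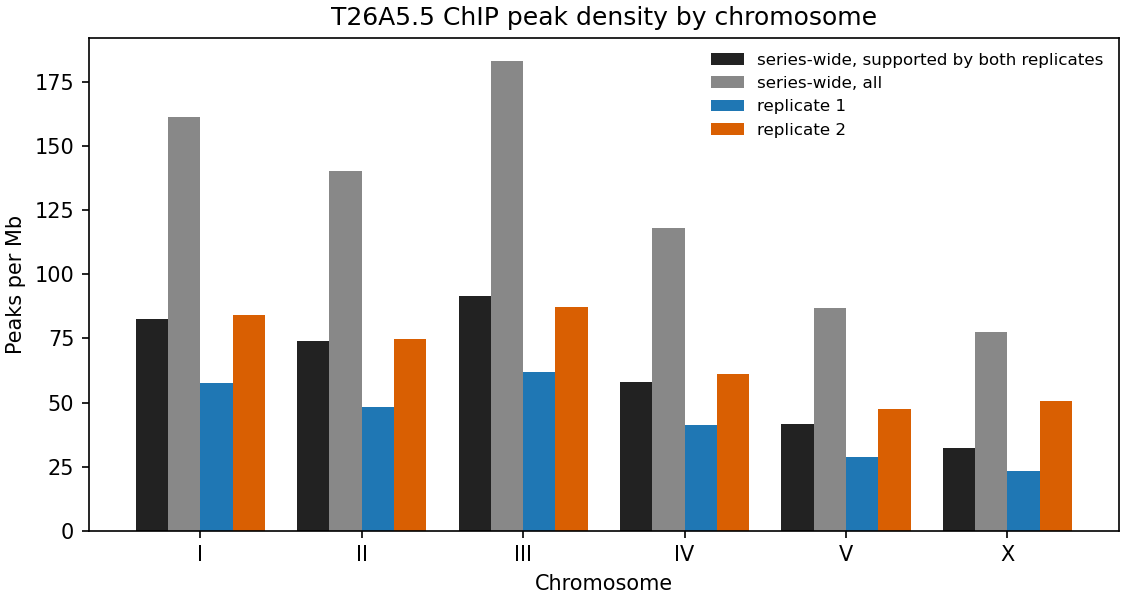
Bars give peaks per Mb on each chromosome for the supported, series-wide, replicate 1 and replicate 2 sets, with chromosome length taken as the highest peak end. X had the lowest density in the supported, series-wide and replicate 1 sets (32.3, 77.4 and 23.5 per Mb), and V had the lowest in the replicate 2 set (47.4).

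Along the chromosomes, the densest 1 Mb bins of supported peaks were III 4000001 to 5000000 with 141 peaks, I 9000001 to 10000000 with 122 and II 11000001 to 12000000 with 121. The sparsest were V 17000001 to 18000000 with 13, V 2000001 to 3000000 with 15 and IV 15000001 to 16000000 with 18. In the densest bin, III 4000001 to 5000000, the replicate 1 list held 88 peaks and the replicate 2 list 117. Several series-wide peaks can overlap the same replicate peak, so supported counts are not counts of separate regions called in both replicates. Autosome arms held 60.2 supported peaks per Mb (SD 26.2, 44 bins) and autosome centres 73.9 (SD 24.9, 41 bins), a ratio of 0.815 (two-sided permutation p = 0.0179). Chromosome by chromosome the ratio was 0.764 on III (exact permutation p = 0.00874), 0.685 on V (permutation p = 0.0258), 0.785 on IV (exact permutation p = 0.122), 0.808 on I (exact permutation p = 0.0843) and 0.942 on II (exact permutation p = 0.732), before any correction for 5 tests. On X the arms and the centre had 31.4 and 33.1 supported peaks per Mb, a ratio of 0.949 (exact permutation p = 0.777). The X ratio was 1.00 in the replicate 1 list (exact permutation p = 1) but 1.52 in the replicate 2 list, with 61.0 peaks per Mb in the arms and 40.2 in the centre (exact permutation p = 0.00123), and 1.22 among all series-wide peaks (exact permutation p = 0.036). The arm difference on autosomes was not stable: it was 0.765 in the replicate 1 list (permutation p = 0.0009) but 0.972 in the replicate 2 list (permutation p = 0.662), and 1.06 among all series-wide peaks (permutation p = 0.406). It also lost its call when base pairs covered were compared in place of peak numbers (0.927, permutation p = 0.382) and without chromosome III (0.834, permutation p = 0.0585). Both of these tests permuted bins across autosomes, which differ in density. With bins permuted within each autosome, the ratio of 0.815 in supported peaks had a permutation p of 0.00215.

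**Figure D3:**
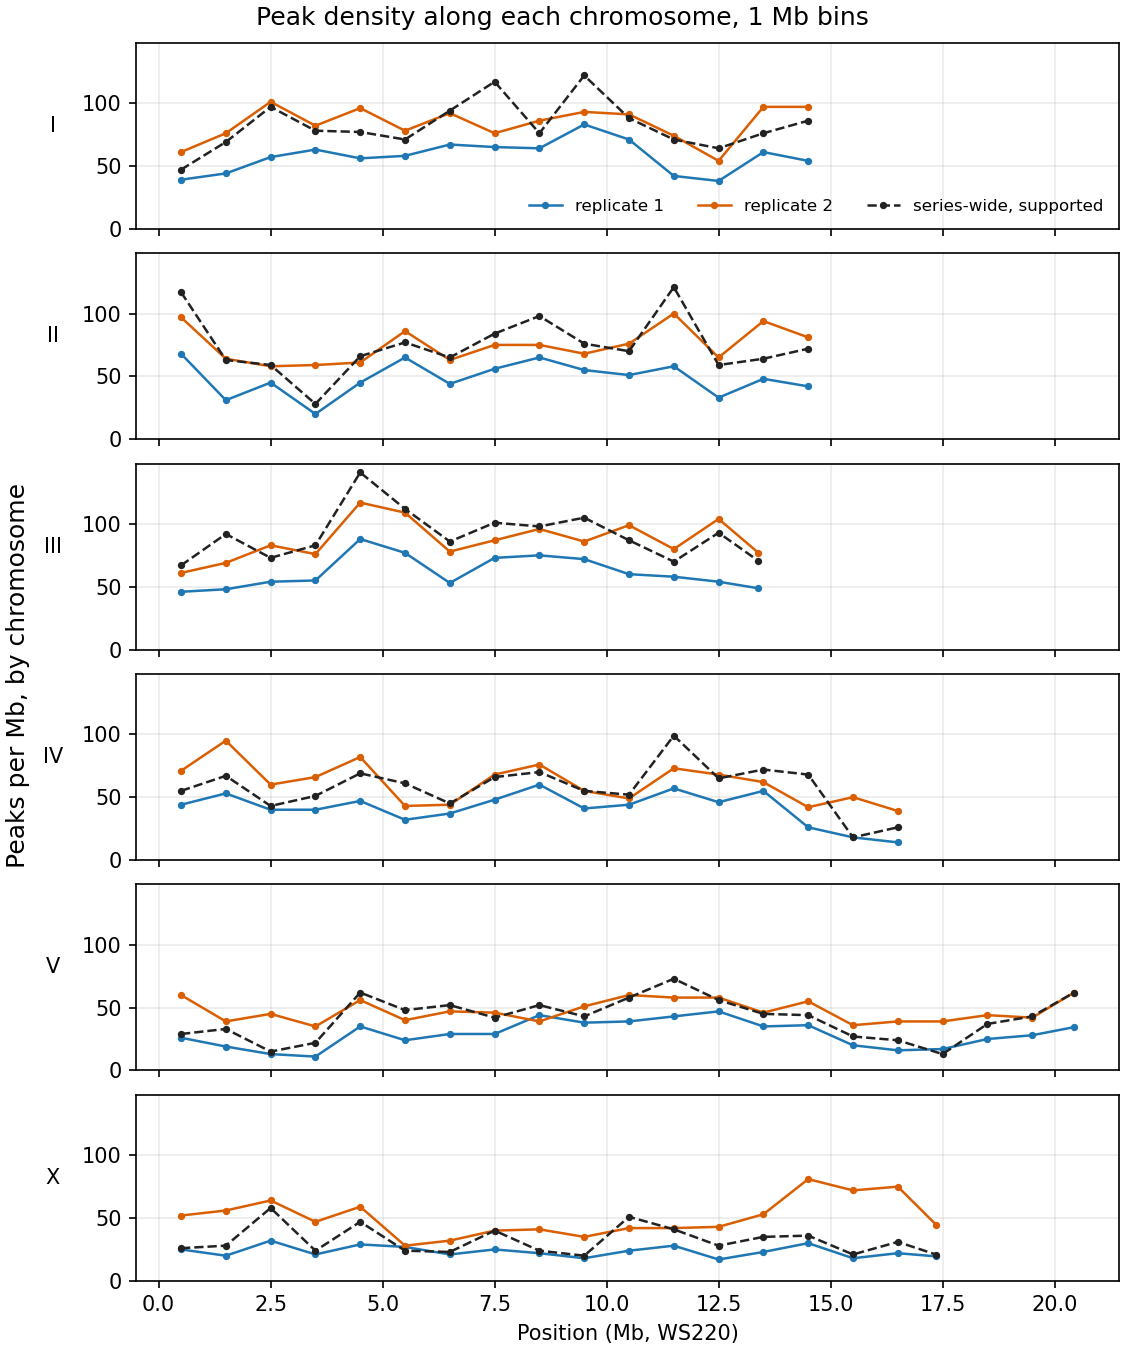
Lines give peaks per Mb in 1 Mb bins along each chromosome (WS220) for the replicate 1, replicate 2 and supported sets, leaving out end bins shorter than 0.5 Mb. The highest supported bin, 141 per Mb, lies at III 4000001 to 5000000, and the lowest, 13 per Mb, at V 17000001 to 18000000.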

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

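The lower density of supported peaks on X kept its direction and stayed past the threshold in all 14 alternatives, planned and added, with ratios to autosomes from 0.427 to 0.734. The replicate 1 and replicate 2 lists taken alone gave 0.512 and 0.734. Those lists were made with MACS and the series-wide list with MACS v2, so they differ from the supported set in more than the replicate. All 14 alternatives permuted bins, which are not independent, and most used the same supported peaks. Arm bins of the other lists were not among them. There the ratio was 0.900 in the replicate 2 list (permutation p = 0.362), 0.591 in the replicate 1 list and 0.622 among all series-wide peaks. The replicate overlap stayed above the shifted lists in all 6 alternatives in each direction, from 42.2% to 82.3% of replicate 1 peaks and, in replicate 2, from 1772 of 6563 peaks to 69.5%. The arm to centre ratio on autosomes, 0.815, kept its direction and its call in 9 of 13 alternatives, with ratios from 0.717 in peaks at or above the median score to 0.826 without chromosome V. It reversed to 1.06 with all series-wide peaks. In the replicate 1 and replicate 2 lists taken alone it was 0.765 and 0.972, no longer past the threshold in the replicate 2 list. It also lost its call with base pairs covered (0.927) and without chromosome III (0.834). The X arm to centre ratio, 0.949 with no call, was 1.22 with all series-wide peaks. In the replicate 1 and replicate 2 lists taken alone it was 1.00 and 1.52. It was past the threshold in the replicate 2 list and among all series-wide peaks. These alternatives were chosen after the data had been seen. The cause was not tested for either ratio. The score correlation, 0.537, was 0.635 with 50% reciprocal overlap and 0.443 in peaks at or above the median score. Support by both replicates, 49.4%, was 48.1% when 50% of the series-wide peak had to be covered, 67.6% in peaks at or above the median score and 50.3% on autosomes. No paired analysis was possible because no file used here holds a value for an input sample, although ChIP and input share replicate numbers. Alternatives that need gene positions, among them peaks per protein-coding gene, were not run. Depth is unknown, so missed peaks cannot be told from absent binding.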

Other observations

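Supported peaks had a median width of 567 bp, measured as series-wide intervals. Peaks shared between the replicate lists were wider, with medians of 1876 bp in replicate 1 and 1554 bp in replicate 2. Of the supported peaks, 1218 (20.0%) were wider than 1000 bp. A further step up, 290 (4.76%) were wider than 2000 bp and 21 (0.344%) wider than 5000 bp. After X 16929241 to 16943487, the widest were II 13817076 to 13828664 (11589 bp, score 64.77) and III 1445962 to 1456264 (10303 bp, score 51.40), neither of them among the 20 highest scores. Width and score were correlated across supported peaks, with a Spearman rho of 0.625. Series-wide peaks also lay close together, since 39.9% of the gaps between neighbours were under 1000 bp. The mean was 12.5% and the maximum 13.3% in 1000 uniform random placements within each chromosome. Such placements ignore regional density and the several series-wide peaks that can overlap one replicate peak, so the cause of the spacing was not tested.

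The strongest replicate 1 peaks with no series-wide peak, chosen after their values were seen, were X 108718 to 114745, III 1299223 to 1303479 and III 7443880 to 7449145, each with a score of 3100 and widths of 6028, 4257 and 5266 bp. Of the replicate peaks absent from the series-wide list, 8 in replicate 1 and 10 in replicate 2 had a score of at least 1000. The highest-scored series-wide peak met by neither replicate was V 11916327 to 11917346, with a score of 62.19.

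Of the tests below, only that of the distance from unsupported peaks to replicate peaks was chosen before its result was seen. No biological explanation was tested for these patterns, since both ChIP samples belong to one group, and each exclusion applies to an explanation as the whole cause.

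Replicate 2 had 13.6% of its peaks on X and replicate 1 had 9.90%, a difference of 3.72 percentage points (95% bootstrap interval over bins 2.06 to 5.41). A longer list with weaker peaks was not the whole cause, because the 4200 highest-scored replicate 2 peaks had 12.4% on X, 2.52 points above replicate 1 (0.826 to 4.27). Joining of neighbouring sites into wider peaks in replicate 1 was not the whole cause either, because X held 13.1% of the base pairs covered in replicate 2 and 10.2% in replicate 1 (difference 2.95 points, 1.76 to 4.15). Peaks absent from the series-wide list lay on X more often than those present in replicate 2 (22.1% against 11.8%) and also in replicate 1 (24.3%, 9 of 37, against 9.78%), so this contrast is not particular to replicate 2. The replicate 2 peaks present in the series-wide list had an X share 1.91 points above that of all replicate 1 peaks (0.569 to 3.33). This is smaller than the 3.72 points for all replicate 2 peaks. A difference in the replicate 2 ChIP or input library stays open, because with 1 library for each replicate and no input values it cannot be told apart from a difference between the embryo samples.

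Of the series-wide peaks, 1866 met a peak of neither replicate. Random noise unrelated to the enriched regions did not account for them as a set, because their median distance to the nearest replicate peak was 2467 bp, against a mean of 6333 bp and a lowest value of 5215 bp for shifted positions. Within 1000 bp of a replicate peak lay 26.7% of them, against 13.2% of shifted positions. Shifting also moves the peaks out of regions of high or low peak density, so noise that follows regional density was not tested. A more permissive cut-off in the series-wide list may account for part, since 0.081% of the highest 10% by score lacked support. This stays open because the share did not fall steadily, at 21.6% in the lowest 10% and 29.8% in the next 10%.

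Replicate 2 peaks were absent from the series-wide list more often than replicate 1 peaks, at 17.7% against 0.881%. Weak peaks alone, as ranked by score within each list, were not the whole cause, because among the 4200 highest-scored peaks of each replicate the 420 lowest were absent in 19.8% of cases in replicate 2 (16.2 to 23.8) and 2.86% in replicate 1 (1.64 to 4.93). Whether the series-wide list was made from replicate 1 alone was not settled. Of its highest 10% by score, 4.45% lacked a replicate 1 peak (3.44 to 5.75) and 0.405% lacked a replicate 2 peak (0.173 to 0.944). The replicate 2 list was longer and covered 13.4 Mb against 10.4 Mb in replicate 1, which by itself makes a missing replicate 2 peak less likely. The lists were not brought to equal length for this test. Earlier forms of both tests were replaced: the lowest 10% of the whole replicate 2 list, 48.6% absent, lay at lower ranks than the replicate 1 list reaches, and weak replicate 1 signal could also give the 61.0% of series-wide peaks outside replicate 1 that met a replicate 2 peak. The series-wide list may also weight the replicates unequally in some way that these lists do not test.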
